A study of Mus musculus with 15 samples.

How the data were processed

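Total RNA from the hippocampus of 15 male C57BL/6J mice, an inbred laboratory strain, was measured on 15 single-colour Agilent mouse oligonucleotide arrays, 1 array per mouse. Per the labels' protocols, RNA was isolated with TRIzol and only samples of high RNA integrity were kept. It was then amplified and labelled with Cy3. Groups were taken from the sample labels. They give 5 control arrays, 5 arrays of mice 1 h after the first extinction trial (E1) and 5 arrays of mice 1 h after the low-freezing extinction trial (ELF), which the design text identifies as trial 5. The sample names call the control mice naive, whereas the design text describes them as exposed to the conditioning context without the shock. Both descriptions are kept open here, and the labels give no time between the last handling of a control mouse and RNA isolation. The labels describe the 5 samples of each group as biological replicates.

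Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, which gave for each of 45018 spots a mean intensity, a local background intensity and a processed intensity that the software had background-subtracted and detrended within the array. Other columns, per the file headers, are flags of 0 or 1 for spots that were well above background, saturated or outliers. The authors' deposited value table holds log2 values of the same spots with medians between 8.68 and 8.92 per array. These values followed log2 of the mean spot intensity closely (Pearson's r across spots at least 0.996 on each array), and so were taken as a log2 scale with no inversion. How the authors normalized them between arrays is not given in the sources used here. The submitters' processing notes name Agilent Feature Extraction and limma. The array design's probe coordinates are on the mouse build mm7, per the file headers.

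The processed intensity was used for the reported fit. The 1639 control spots and spots marked as outliers were left out. Each log2 intensity was set relative to the 75th percentile of its own array, and spots of the same probe were averaged to 41174 probes. A probe was kept if it was well above background on at least 5 of the 15 arrays, which left 38457 probes. For each gene name the probe with the highest mean over all 15 arrays was used, which gave 26117 genes. Through their transcript accessions, 22951 probes matched a RefSeq gene table of GRCm38.p6, which was used for symbols only. Names of the array design are printed, some of them old, and the current symbol is given where it differs and the gene is discussed. Coordinates are those of the probe in mm7. No genome sequence was used here. Signal over background limits the precision of dim genes, and the number of arrays limits all comparisons. Between 83.5% and 97.2% of the spots of an array were well above background. For a gene below background on every array of a group only a bound is printed. It sets the mean of the brighter group against the mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background.

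Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 15 arrays and no covariate in the model. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 26117 genes. For 31 gene lists with at least 5 measured members, fixed before the data were examined, camera was run with the preset inter-gene correlation of 0.01 on 26052 genes without missing values, with adjustment over the 31 lists. It was repeated with the correlation estimated from the data, with fry, and with the slide in the model. The number of members past the threshold was counted over all genes and adjusted over the list alone. The pipeline was tested on simulated data with the spread of the real genes, in which 67, 67 and 66 of 26052 genes were changed by 0.5, 1 and 2 on the log2 scale. In the simulation of E1 versus control, 90.9% of genes changed by 2 on the log2 scale were recovered, 73.1% of those changed by 1 and 29.9% of those changed by 0.5. For ELF versus control these shares were 92.4%, 68.7% and 26.9%, and for ELF versus E1 92.4%, 67.2% and 25.4%. The data of these fits held no slide effect and genes drawn independently of each other. The shares therefore need not hold for the real arrays, where arrays of a slide were correlated. With slide as a fixed block the shares in that order of sizes fell to 57.6%, 16.4% and 0% for E1 versus control, 37.9%, 0% and 0% for ELF versus control, and 68.2%, 29.9% and 1.49% for ELF versus E1, so a gene that misses the threshold with the block is not thereby shown to be unchanged.

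Slides of up to 4 arrays, read from the array identifiers, were treated as batches, and all were scanned on 1 day. Slide 1 held 4 control arrays. Slide 2 held 1 control and 3 E1 arrays, slide 3 held 2 E1 and 2 ELF arrays, and slide 4 held 3 ELF arrays. With slide as a fixed block, the difference between E1 and control comes only from slide 2 and that between ELF and E1 only from slide 3. ELF and control share no slide, so their blocked difference is the sum of both. The consensus correlation of arrays of a slide in the random-block fit was 0.467. The labels number the arrays of each group from 1 to 5 but name separate animals and no shared litter or day. Deviations from the group mean of same-numbered control and E1 arrays correlated at 0.142 to 0.299 in all 5 pairs, with 2 of 5 closest to their own number, so for that comparison the numbers pair the arrays by a hint from the data alone. Of the 120 ways to number the E1 arrays, 4 gave 5 such correlations over 0.1. The reported fit has no replicate block.

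Genes to be named were fixed before the data were examined. For each comparison these were the 8 genes with the largest positive and the 8 with the largest negative log2 difference among called genes, and the 4 and 4 largest that also had an unadjusted p under 0.05 in the same direction with slide as a fixed block. Up to 4 members with the lowest p of each list discussed were added. Igf2, Igfbp7, Ttr, Fos, Arc, Egr1, Npas4, Bdnf and Fkbp5 were named in each comparison whatever their values. Where fewer than 8 genes passed in a direction, those that passed were named, and the 4 genes with the lowest p if none passed. Clone names, locus numbers, accessions and probe names were passed over in the parts based on size. Genes with a missing value that left the slide block without an estimate were passed over in the part that uses the block, which was decided after values had been seen and changed the genes named there. Alternatives were quantile normalization, the median of kept probes as the shift, normexp background correction, the authors' values, no filter or a stricter filter on dim probes, slide as a fixed or random block, arrays of a shared slide only, the replicate number as a block, a fit of only the groups compared, the mean of a gene's probes, eBayes with trend and robust estimation, array weights, an adjusted p under 0.01, the mean of choroid plexus markers as a covariate, and each array left out. Quantile normalization together with the slide block, a fit without ELF arrays 2 and 4, and the replicate block in a fit of only the control and E1 arrays were chosen after seeing the data.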

Results

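The study followed the extinction of contextual fear, in which mice that received a footshock in a box are returned to it at intervals of 24 h without the shock until they freeze less. Transcripts of the hippocampus, a brain region needed for this form of memory, were measured in 5 control mice, 5 mice sampled 1 h after the first extinction trial, when freezing was high (E1), and 5 mice sampled 1 h after trial 5, when freezing had fallen (ELF). The array's 75th percentile intensity lay between 1445 and 2929. Values below are log2 intensities relative to that percentile, given as mean ± SD over 5 arrays unless another n is stated. Differences carry the standard error (SE) of the limma fit, and all adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment.

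The comparison of E1 with control asks what the hippocampus expressed shortly after the first return to the shock context. Several immediate early genes, which neurons switch on within minutes of firing, rose. Fos (probe at chromosome 12, 83478431 to 83478490 of mm7), a subunit of the AP-1 transcription factor, was -0.75 ± 0.35 in E1 and -2.23 ± 0.33 in control, a difference of 1.47 (SE 0.25, adjusted p = 0.0351). Arc (chromosome 15, 74749717 to 74749776), whose product regulates AMPA receptor traffic at synapses, rose by 1.16 (SE 0.16, adjusted p = 0.00998) from 2.82 ± 0.04 to 3.99 ± 0.24. The zinc finger transcription factor Egr2 rose by 1.22 (SE 0.20, adjusted p = 0.0325), and Ier2, Dusp1 and Axud1 (now Csrnp1) rose by 0.85, 0.81 and 0.78. Cxcl5 (chromosome 5, 90732453 to 90732512), a chemokine gene, fell by 2.0 (SE 0.20, adjusted p = 0.00228). In 10 fits with 1 array left out, the limma threshold was missed by Fos in 8 (highest adjusted p = 0.113), Arc in 0 (highest adjusted p = 0.0472), Egr2 in 8 (highest adjusted p = 0.115) and Cxcl5 in 0 (highest adjusted p = 0.0131).

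Of the 47 measured activity-regulated genes, 9 rose and none fell over all genes tested, and 23 rose adjusted over the list alone. Their median difference was 0.42, against 0.04 for all genes (camera adjusted p = 1.31e-15, and adjusted p = 0.00498 with an estimated correlation). Blocked by slide, the median was 0.36, a difference that rests on slide 2 and its 1 control array. On slide 2, where 3 E1 arrays and 1 control array lay side by side, 37 of the 47 were higher in E1. The members of fixed interest that did not pass had differences of 0.61 for Egr1 (adjusted p = 0.106), 0.73 for Npas4 (adjusted p = 0.195) and 0.38 for Bdnf (adjusted p = 0.1).

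**Figure D1:**
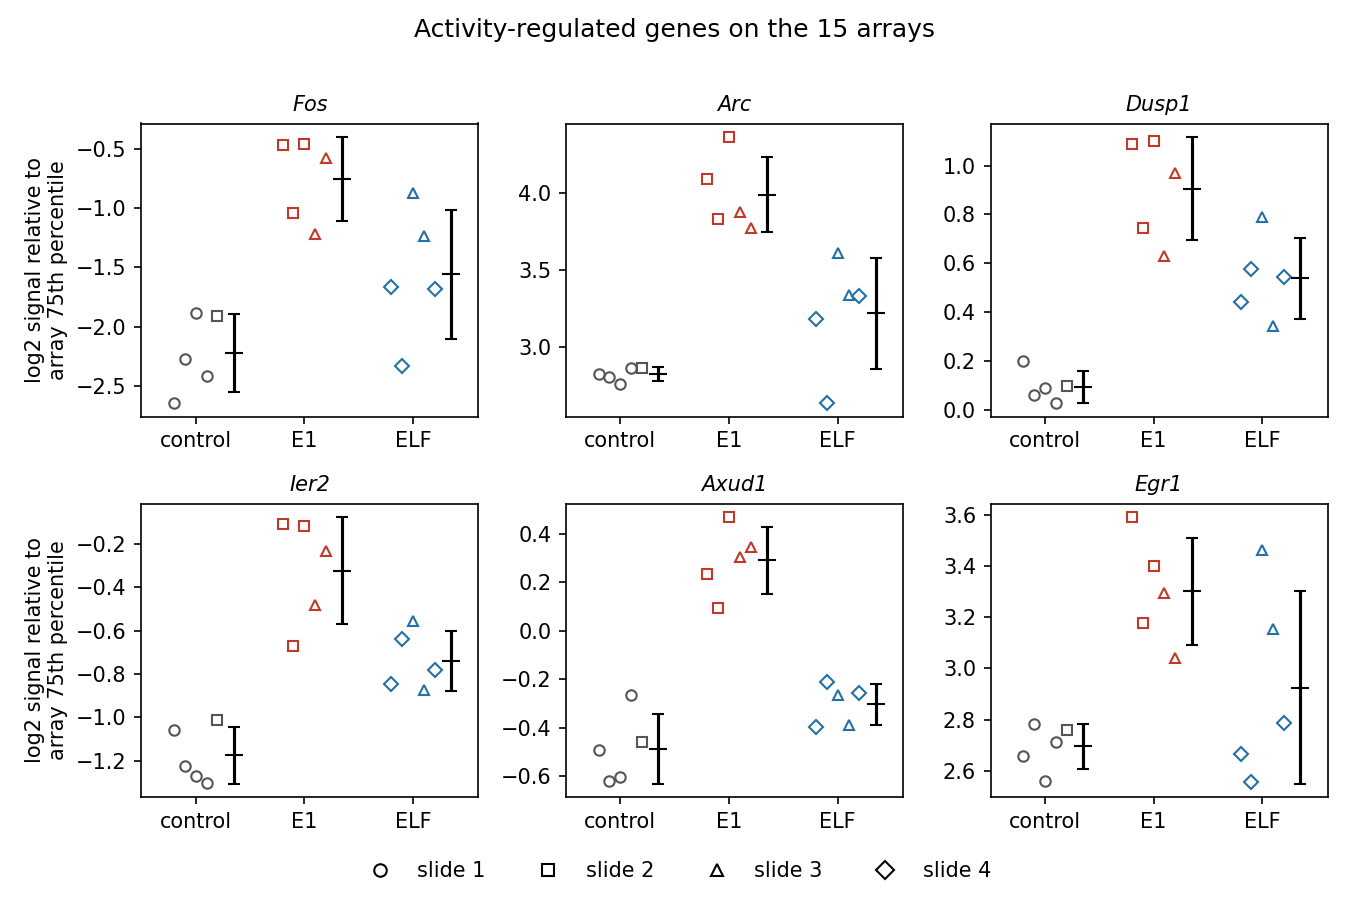
Log2 intensity relative to the array's 75th percentile of 6 activity-regulated genes on the 15 arrays, by group, with the slide as the symbol and the mean ± SD of each group beside its points (n = 5). Arc lies between 3.77 and 4.36 on the E1 arrays and at most 2.87 on the control arrays, those of both slides included.

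Genes that respond to glucocorticoids, the stress hormones, were higher as a list in E1. Of 27 members 1 rose over all genes, and 9 adjusted over the list alone, with a median difference of 0.26 (camera adjusted p = 1.92e-07). The adjusted p was 0.0831 with an estimated correlation, past no threshold. With slide as a block at the preset correlation the list also passed, though that difference rests on 1 control array. Dusp1, the member that rose, belongs to the activity-regulated list too, as do 2 other members. Nfkbia differed by 0.63 (adjusted p = 0.0519), Sgk (now Sgk1) by 0.54 (adjusted p = 0.0525) and Ddit4 by 0.48 (adjusted p = 0.0519). Fkbp5, a classical glucocorticoid target, differed by 0.16 (SE 0.13, adjusted p = 0.651). Among circadian clock genes, Dbp, an output transcription factor of the clock, rose by 0.92 (adjusted p = 0.0351), while the list of 19 did not stand apart (camera adjusted p = 0.439). Dbp missed the threshold in 8 of 10 fits with 1 array left out (highest limma adjusted p = 0.134).

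Endothelial genes were lower in E1. Of 18 endothelial markers 2 fell, Cldn5, a tight junction protein of brain vessels, by 0.94 (SE 0.14, adjusted p = 0.02) and Kdr, a receptor of vascular endothelial growth factor, by 0.87 (SE 0.16, adjusted p = 0.0488). Adjusted over the list alone 6 fell. In 10 fits with 1 array left out, Cldn5 missed the limma threshold in 5 (highest adjusted p = 0.0783) and Kdr in 9 (highest adjusted p = 0.181). The list's median was -0.33 (camera adjusted p = 9.96e-12, and adjusted p = 0.0849 with an estimated correlation). In the fit blocked by slide, where the difference rests on 1 control array, it was -0.22. Without control 1, which stood apart for this list, the unblocked median was -0.24 (camera adjusted p = 2.28e-10). Outside that list, Sox18, a transcription factor of vessel formation, fell by 1.11 (adjusted p = 0.00315) and Edn1, which encodes the vasoconstrictor endothelin-1, by 1.27 (adjusted p = 0.0205). Eomes, a marker of neuronal progenitors, fell by 0.84 (adjusted p = 0.0124), Sln by 1.19 and Ebf3 by 1.04. Another probe of Ebf3 differed in the opposite direction. The chemokine gene Ccl3 fell by 0.78 (adjusted p = 0.00263). In the same 10 fits the threshold was missed by Edn1 in 6, Eomes in 1, Sln in 8 and Ebf3 in 7 (highest adjusted p = 0.12), and by Sox18 and Ccl3 in none. Blocked by slide, the differences were -0.62 for Cldn5, -0.31 for Kdr, -0.78 for Sox18, -0.57 for Edn1, -0.97 for Eomes and -0.74 for Ccl3.

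Further lists that passed at the preset correlation were thalamus and habenula markers, higher by a median of 0.23 (adjusted p = 0.0154), meningeal and fibroblast markers, lower with a median of -0.18 (adjusted p = 0.0154), and proteasome genes, higher by 0.09 (adjusted p = 0.0339). None of these held with an estimated correlation, with adjusted p = 0.804, adjusted p = 0.892 and adjusted p = 0.892 in that order. Among thalamus and habenula markers Ramp3 rose by 0.86 (adjusted p = 0.0351), and missed the limma threshold in 8 of 10 fits with 1 array left out. Blocked by slide, where the difference rests on 1 control array, the thalamus and habenula list remained higher and the proteasome list did not pass. The meningeal list then had a median of 0.06 and did not pass. With 1 array left out, camera's adjusted p missed the threshold for the thalamus and habenula list without control 5 (0.103), E1 3 (0.0722), the meningeal list without control 1 (0.151), control 3 (0.0764), E1 3 (0.0715), E1 4 (0.105), the proteasome list without control 3 (0.0567), control 5 (0.103), E1 3 (0.0706).

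In all, 35 genes rose and 14 fell of 26117, and 3419 had an unadjusted p under 0.05. The split was 369 higher and 77 lower with quantile normalization, and 251 and 40 with the median as the shift. Leaving out 1 array gave 1117 genes without control 5, 8 without control 2, 12 without control 3, 14 without E1 3 or E1 5, 15 without control 1 or E1 4, 16 without control 4 and 22 without E1 1. The largest fitted increases were in dim genes. Kng1 differed by 3.08 (0.12 blocked by slide) and Olfr545 by 2.55 (0.87 blocked by slide). Each was well above background on only 1 of 5 control arrays, so the size of both is uncertain. Defb6 was not well above background on any control array and was on 3 of 5 E1 arrays, at least 2.12-fold higher (adjusted p = 0.0417), a bound that does not hold within slide 2, where its log2 difference was 0.80. Pp11r (now Endou) rose by 1.80, Myo15 by 1.75 and Ppp1r14d by 1.61 (both with 4 control arrays, all of slide 1), Trp53i5 (now Ano9) by 1.60, Clspn by 1.47 and Zcchc5 (now Rtl3) by 1.40. In 10 fits with 1 array each left out, the limma threshold was missed by Kng1 in 9, Olfr545 in 9, Defb6 in 8, Pp11r in 8, Myo15 in 8, Ppp1r14d in 7, Trp53i5 in 7, Clspn in 8 and Zcchc5 in 1 (highest adjusted p = 0.184). Slide limits this count: with slide as a fixed block 3 genes passed, none of them among the 49, and with a random block none did by limma. The fixed block rests on slide 2, where 1 control array stands against 3 E1 arrays, and in simulated data it recovered 16.4% of the genes changed by 1 on the log2 scale. Of the 49, 47 could be fitted with the block, all 47 kept their sign and 29 had an unadjusted p under 0.05, with differences of 1.25 for Fos, 1.06 for Egr2, 1.23 for Arc and -1.60 for Cxcl5. Others shrank, to 0.42 for Pp11r, 0.46 for Clspn, 0.77 for Trp53i5 and 1.02 for Zcchc5, and Myo15 and Ppp1r14d had no blocked estimate. The arrays of slide 2 also helped to choose the 49 genes, which favours a kept sign, so the kept signs are no separate support.

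The replicate number as a block, a pairing of control with E1 arrays that rests on the data and not on the labels, moved these calls in both directions. In the fit of 15 arrays it called 12 genes, 6 higher and 6 lower, with limma adjusted p = 0.0549 for Fos, 0.0559 for Egr2, 0.0601 for Dbp, 0.0549 for Cldn5, 0.0559 for Kdr, 0.0549 for Ebf3, 0.0613 for Sln and 0.0639 for Ramp3. Kng1, Olfr545, Defb6, Pp11r, Myo15, Ppp1r14d, Trp53i5, Clspn and Zcchc5 missed the threshold too. In a fit of only the 10 control and E1 arrays it called 3148 genes, 2406 higher and 742 lower, among them all 49, Egr1 (limma adjusted p = 0.0245), Nfkbia (adjusted p = 0.0215), Sgk (adjusted p = 0.0249) and Ddit4 (adjusted p = 0.0162). Other named genes that passed there were Abcb1a, Ccl2, Emcn, Gm129 (now Ciart), Nfkb1, Per1, Rgs16, Synpo2 and Top2a. Of the 120 possible numberings of the E1 arrays, 2 called at least as many in that fit, that of the labels included, and the median was 0. With the block, 5 lists passed in either fit. The proteasome list did not (camera adjusted p = 0.0715 with 15 arrays and adjusted p = 0.134 with 10), nor did the thalamus and habenula list with 10 arrays (adjusted p = 0.163), where choroid plexus markers were lower (median -0.20, adjusted p = 0.00543).

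The comparison of ELF with control asks what differed at the trial when freezing had fallen. Of 18 endothelial markers 8 fell and none rose in the fit without a block, and 13 fell adjusted over the list alone, while the list did not pass with an estimated correlation (camera adjusted p = 0.133) or blocked by slide (camera adjusted p = 0.448). Flt1, a receptor of vascular endothelial growth factor, fell by 1.14 (SE 0.22, adjusted p = 0.0287) from 2.19 ± 0.43 to 1.05 ± 0.29. Abcb1a, a drug efflux pump of the blood-brain barrier, fell by 1.20 (SE 0.17, adjusted p = 0.0174). Kdr fell by 0.99, Cldn5 by 0.74 and Ptprb, an endothelial phosphatase, by 1.66 (adjusted p = 0.035). In 10 fits without 1 array each, Flt1 missed the limma threshold in 6 (highest adjusted p = 0.0961) and Abcb1a in 2 (highest adjusted p = 0.0689). Of 14 mural cell markers 2 fell, Rgs5 by 0.65 and Mcam by 0.33. The threshold was missed in those fits by Kdr in 2, Cldn5 in 6, Ptprb in 6, Rgs5 in 6 and Mcam in 8 (highest adjusted p = 0.113). Blocked by slide none of these genes passed, and the differences were -0.13 for Flt1, -0.47 for Abcb1a, -0.24 for Kdr, -0.12 for Cldn5, -0.57 for Ptprb, -0.58 for Rgs5 and -0.32 for Mcam, against -0.22 for the median of all genes.

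The endothelial list had a median of -0.65 at the preset correlation (camera adjusted p = 4.2e-14). As given above, it passed neither with an estimated correlation nor blocked by slide. In the fit blocked by slide the median was -0.45 against -0.22 for all genes. Without control 1, which stood apart for this list, the unblocked median was -0.56 (camera adjusted p = 1.63e-14). The mural list passed only without the block (camera adjusted p = 0.00886, with the block adjusted p = 0.733, and adjusted p = 0.494 with an estimated correlation), and missed the threshold without ELF 1 (camera adjusted p = 0.0528).

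Within the insulin-like growth factor system, Igf2 and Igfbp7 were called lower. Igf2 (chromosome 7, 139078075 to 139078135), a growth factor made by the choroid plexus and meninges, was 3.68 ± 0.35 in control, 3.37 ± 0.22 in E1 and 2.78 ± 0.45 in ELF, and fell by 0.90 from control to ELF (SE 0.21, adjusted p = 0.0477). Igfbp7, which encodes a secreted binding protein, fell by 0.97 (SE 0.18, adjusted p = 0.0256). Igfbp2 differed by -0.81 (adjusted p = 0.0649) and Igfbp1 by 0.50 (adjusted p = 0.0618). Of 23 measured members these 2 fell and none rose, 3 fell and 2 rose adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.222). Blocked by slide, the differences were -0.73 for Igf2 and -0.66 for Igfbp7, with limma adjusted p = 0.353 and adjusted p = 0.293. With the mean of choroid plexus markers as a covariate, Igf2 differed by -0.52 (SE 0.19, limma adjusted p = 0.201). In 10 fits with 1 array left out, the limma threshold was missed by Igf2 in 7 (highest adjusted p = 0.144) and by Igfbp7 in 4 (highest adjusted p = 0.0961). Without the third ELF array Igf2 differed by -0.73 (limma adjusted p = 0.0622). The blocked differences of Igf2 and Igfbp7 draw on slide 3, which holds that array, and are no separate support.

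Choroid plexus markers, genes of the tissue that makes cerebrospinal fluid, had a median of -1.07 over 24 members (camera adjusted p = 6.38e-13, and adjusted p = 0.425 with an estimated correlation). No member passed over all genes and 8 were lower adjusted over the list alone. A single array carried much of the shift: Ttr, an abundant choroid plexus transcript, was -1.81 on the third ELF array and between 3.35 and 4.02 on the other 4. Ttr as a group was 2.6 ± 2.47 in ELF and 4.33 ± 0.28 in control (adjusted p = 0.236). Prlr differed by -1.42 (adjusted p = 0.0734), Sostdc1 by -1.27 (adjusted p = 0.0839) and Slc39a4 by -0.91 (adjusted p = 0.059). Without that array the list's median was -0.55 (camera adjusted p = 5.3e-13). Blocked by slide, with all arrays, it was -1.45. The blocked value draws on slide 3, which holds the third ELF array, so it is no support separate from that array.

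**Figure D2:**
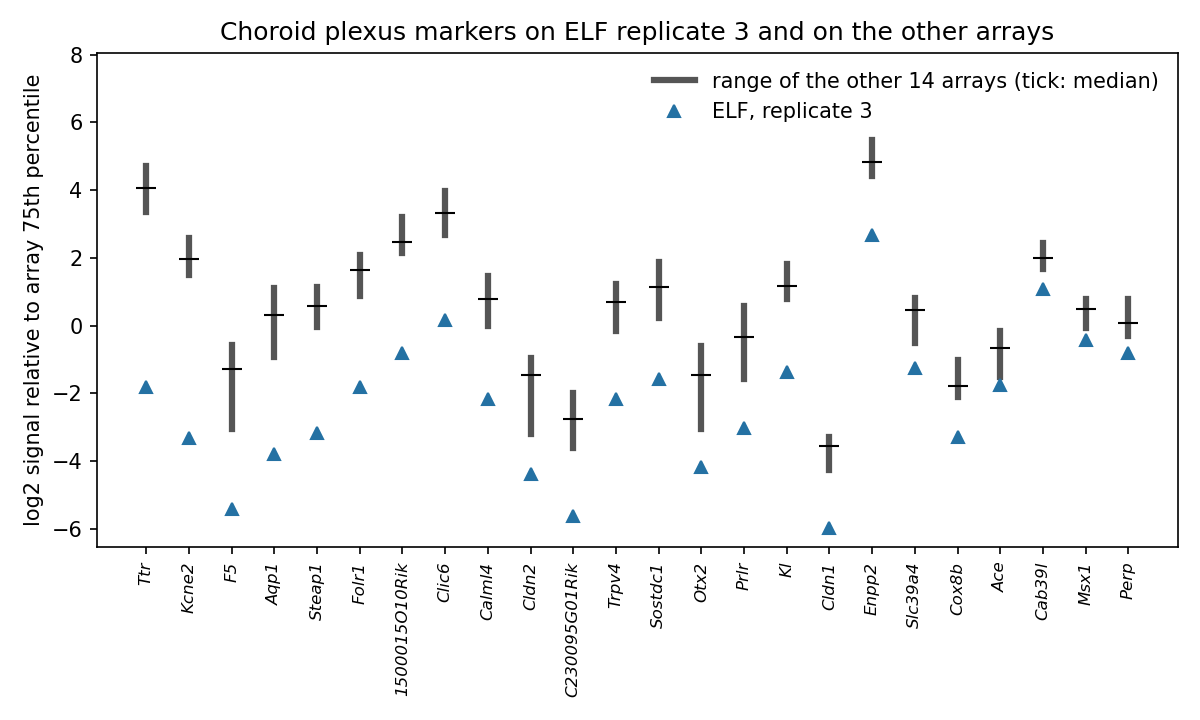
Log2 intensity relative to the array's 75th percentile of the 24 measured choroid plexus markers, with the third ELF array as a triangle and the range and median of the other 14 arrays as a bar and tick. All 24 markers are lower on the third ELF array than on each of the other 14.

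Activity-regulated genes were higher in ELF than in control by a median of 0.21 (camera adjusted p = 0.00845, and adjusted p = 0.425 with an estimated correlation). Of 47 members 3 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone. Arfl4 (now Arl4d) rose by 0.83, Gadd45g by 0.55 and Dusp1 by 0.44, while Klf4, a transcription factor also found in endothelium, fell by 0.89. Blocked by slide these 4 differences were 0.49, 0.40, 0.65 and -0.06, and in 10 fits with 1 array left out the limma threshold was missed by Arfl4 in 4, Gadd45g in 4, Dusp1 in 8 and Klf4 in 7. Fos differed by 0.67 (SE 0.25, adjusted p = 0.14), Arc by 0.39 (adjusted p = 0.158), Egr1 by 0.23, Npas4 by -0.13 and Bdnf by 0.04, none past the threshold. In the fit blocked by slide the list's median was 0.19 against -0.22 for all genes (camera adjusted p = 3.41e-06). A blocked difference here adds E1 minus control on slide 2 to ELF minus E1 on slide 3. The list's medians were 0.36 against -0.04 for all genes on slide 2, and -0.16 against -0.18 on slide 3. Relative to all genes the blocked shift thus comes from E1 on slide 2, with its 1 control array, and is no separate evidence for ELF. Without the third ELF array camera's adjusted p was 0.0703, and without the fourth 0.181.

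Glucocorticoid-responsive genes were higher by a median of 0.19 (camera adjusted p = 0.00845, and adjusted p = 0.425 with an estimated correlation, and 0.0507 blocked by slide), with Ddit4 higher by 0.43 (adjusted p = 0.04, missed in 8 of 10 fits with 1 array left out). Fkbp5 differed by 0.13 (adjusted p = 0.589). Cytosolic ribosomal protein genes were lower, with a median of -0.11 (camera adjusted p = 0.00845), and -0.50 blocked by slide (camera adjusted p = 0.0153), with none of 75 called. They did not pass with an estimated correlation (adjusted p = 0.817) or with quantile normalization (camera adjusted p = 0.617). With 1 array left out their unblocked median lay between -0.20 and -0.02. At the preset correlation, interferon and cytokine genes and histone and DNA modifying enzymes were lower and proteasome genes and microglia markers higher. Their medians lay at -0.11, -0.03, 0.14 and 0.22 in that order. With an estimated correlation these 4 lists had adjusted p = 0.494, adjusted p = 0.425, adjusted p = 0.747 and adjusted p = 0.659, and blocked by slide adjusted p = 0.448, 0.781, 0.0568 and 0.781. With 1 array left out, camera's adjusted p missed the threshold for the glucocorticoid list without ELF 4 (0.0738), the ribosomal list without ELF 5 (0.14), the interferon and cytokine list without ELF 1 (0.0562), the histone and DNA enzyme list without control 2 (0.0558), control 5 (0.111), ELF 1 (0.0929), ELF 2 (0.129), the proteasome list without control 5 (0.0808), ELF 4 (0.448), the microglia list without control 1 (0.0645), control 5 (0.0842), ELF 1 (0.0577), ELF 3 (0.0686), ELF 4 (0.341).

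Over all genes 378 rose and 170 fell, and 6001 had an unadjusted p under 0.05. Among the genes that fell most, Sh3rf2 fell by 1.39, the transcription repressor Bach1 by 1.20, the chemokine gene Cxcl12 by 1.09, Elovl7 by 1.06 and Eltd1 (now Adgrl4), an endothelial receptor gene, by 1.05. Blocked by slide these 5 differences were -1.34, -1.32, -0.18, -0.99 and -0.30. Another probe of Cxcl12 differed in the opposite direction. Genes that fell and were also lower with the block included Slco1c1, a thyroid hormone transporter of brain vessels and glia, by 0.73 (adjusted p = 0.0441, -0.98 with the block), Sfrp1, a Wnt antagonist, by 0.82 (adjusted p = 0.0431, -1.14 with the block), Pltp by 0.80 and Trim30 (now Trim30a) by 0.83. The blocked difference draws on slide 3, which holds the third ELF array with its low choroid plexus markers, so for genes that fall with those markers the block is no separate support. With the marker mean as a covariate the differences were -0.51 for Slco1c1 (limma adjusted p = 0.187), -0.53 for Sfrp1 (adjusted p = 0.184), -0.75 for Trim30 (adjusted p = 0.128) and -0.62 for Pltp (adjusted p = 0.0305), and 148 genes were called in place of 548. Without that array the difference was -0.65 for Slco1c1 (limma adjusted p = 0.063) and -0.69 for Sfrp1 (adjusted p = 0.0577), so most of each difference remained. Genes that rose and were also higher with the block included Cd83, by 0.46 (adjusted p = 0.0244), Clca3 (now Clca1), by 1.06, and Olfr120, by 0.92. With the choroid plexus covariate these 3 missed the threshold too (limma adjusted p = 0.0763, adjusted p = 0.0901 and adjusted p = 0.127), as did Dusp1 (adjusted p = 0.2). Their differences then were 0.42 for Cd83, 1.03 for Clca3, 0.87 for Olfr120 and 0.32 for Dusp1, so those of Cd83, Clca3 and Olfr120 moved little. The largest fitted increases were in dim genes, of uncertain size: Olfr545 by 2.44, Tpbpa by 2.26, Tlr8 by 2.22, Olfr91 by 1.90 and Klra17 by 1.83, each well above background on 1 of 5 control arrays. Spag4l (now Sun5) rose by 1.81 (0.57 with the block) and Ppp1r14d by 1.75 (with the 4 control arrays of slide 1). Capza3 was not well above background on any control array and was on 4 of 5 ELF arrays, at least 2.33-fold higher (adjusted p = 0.0388). The slide block turned the direction of Tpbpa (-0.47), Tlr8 (-1.41), Olfr91 (-0.29), Klra17 (-1.07) and Capza3 (-0.73), and left Olfr545 at 1.03. Of the genes in this paragraph, 10 fits with 1 array left out missed the limma threshold for Sh3rf2 in 6, Bach1 in 4, Cxcl12 in 5, Elovl7 in 3, Eltd1 in 2, Slco1c1 in 7, Sfrp1 in 6, Pltp in 2, Trim30 in 6, Cd83 in 3, Clca3 in 3, Olfr120 in 5, Olfr545 in 3, Tpbpa in 3, Tlr8 in 8, Olfr91 in 7, Klra17 in 8, Spag4l in 2, Ppp1r14d in 2 and Capza3 in 7.

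The authors' values gave 781 higher and 806 lower genes. Leaving out 1 array gave no gene by limma without control 2 or control 3, 36 without control 1, 112 without control 4, 2110 without control 5, 137 without ELF 1, 209 without ELF 2, 5123 without ELF 4 and 210 without ELF 5. Of the 548 genes, 371 kept their sign with slide as a fixed block, 175 took the opposite sign, and 38 had the same sign at an unadjusted p under 0.05. That block called 81 genes, none shared with the 548, a random block called none by limma, and a fit of only these 2 groups called none, against 6001 genes at an unadjusted p under 0.05 in the reported fit. In 100 simulations without any group change, added after seeing the data, in which arrays of a slide were correlated at 0.467 as in the random-block fit, 461 genes on average and at most 666 were called for ELF versus control, so the 548 lie within the range that a slide effect of that size gives. For E1 versus control the mean was 11 and the highest 42, against 49. Genes were drawn independently of each other in these simulations, so the ranges may be too narrow. The 49 are not thereby set apart from a slide effect.

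The comparison of ELF with E1 asks how expression differed between mice sampled at high and at low freezing. The groups also differ in the number of trials and in the time since the shock. These cannot be told apart from the fall in freezing. Cxcl5 rose by 1.62 (SE 0.20, adjusted p = 0.025) and Ccl3 (chromosome 11, 83717761 to 83717820) by 0.64 (SE 0.08, adjusted p = 0.025). Both encode chemokines that attract myeloid cells, both had fallen from control to E1, and both were higher on each of the 5 ELF arrays than on any E1 array. Their signals were low, Cxcl5 at -3.54 ± 0.27 in ELF and -5.16 ± 0.37 in E1, though well above background on all of these arrays. The fall from control and the rise to ELF of both genes use the same E1 arrays, so low values there would give both. Genes chosen for passing also tend to part the arrays of the groups, so neither is separate support. No gene fell, and 2517 had an unadjusted p under 0.05 by limma. Slide as a fixed block gave the opposite balance, with 5040 genes called, 698 higher and 4342 lower, and a median of -0.18 over all genes. With quantile normalization and that block 898 were called, 523 higher and 375 lower, and the median was -0.03, so the balance depends on the scaling. On slide 3, the only one with both groups, the difference was 2.01 for Cxcl5 and 0.63 for Ccl3. With quantile normalization neither passed (limma adjusted p = 0.0598 and adjusted p = 0.211), and a random slide block or a fit of only these 2 groups called no gene. Cxcl5 and Ccl3 each missed the threshold in 7 of 10 fits with 1 array left out (highest limma adjusted p = 0.106 and adjusted p = 0.11). Without 1 array, limma called 11 genes (without ELF 3), 10 (without ELF 4), 1 (without E1 2 or E1 3) or none (without any of the other 6).

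Activity-regulated genes were lower in ELF than in E1, with a median of -0.17 against 0.05 for all genes (camera adjusted p = 1.21e-09, and adjusted p = 0.0399 with an estimated correlation). No member passed over all genes; adjusted over the list alone 17 fell and 2 rose. Axud1 differed by -0.59 (adjusted p = 0.0741), Trib1 by -0.71 (adjusted p = 0.121), Arc by -0.77 (adjusted p = 0.207), Nr4a1 by -0.47, Fos by -0.80 (adjusted p = 0.37), Npas4 by -0.86, Egr1 by -0.38 and Bdnf by -0.34. Within slide 3 the list's median was -0.16, close to the -0.18 of all genes there. In the fit of all arrays blocked by slide, the list did not stand apart (camera adjusted p = 0.669).

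Thalamus and habenula markers were lower in ELF than in E1, with a median of -0.22 (camera adjusted p = 1e-06, and adjusted p = 0.15 with an estimated correlation), with Synpo2 at -1.05 (adjusted p = 0.224) and Rora at -0.63 (adjusted p = 0.264). Blocked by slide, that list did not pass (camera adjusted p = 0.577). Cytosolic ribosomal protein genes were lower, with a median of -0.18 (camera adjusted p = 1.46e-09, blocked by slide adjusted p = 0.0025, and adjusted p = 0.558 with an estimated correlation). With quantile normalization the median was -0.04 (camera adjusted p = 0.036). Choroid plexus markers had a median of -0.85 (camera adjusted p = 1.15e-12, and adjusted p = 0.423 with an estimated correlation) and -0.34 without the third ELF array, and within slide 3, which holds that array, -1.57. Igf2 differed by -0.59 (SE 0.21, adjusted p = 0.42), Igfbp7 by -0.53 (adjusted p = 0.4), Ttr by -1.46 (adjusted p = 0.606) and Fkbp5 by -0.04. Without the third ELF array Ttr differed by -0.36. Oxidative phosphorylation, mural, endothelial, glucocorticoid and plasticity kinase lists were lower at the preset correlation. Their medians lay at -0.05, -0.13, -0.14, -0.05 and -0.03. With an estimated correlation they had adjusted p = 0.727, adjusted p = 0.477, adjusted p = 0.516, adjusted p = 0.509 and adjusted p = 0.423, and blocked by slide none of the 5 passed (lowest camera adjusted p = 0.144). With 1 array left out, camera's adjusted p missed the threshold for the oxidative phosphorylation list without ELF 5 (0.201), the endothelial list without ELF 1 (0.073), the glucocorticoid list without E1 3 (0.082), ELF 1 (0.16), ELF 5 (0.13), the plasticity kinase list without E1 3 (0.0754), E1 5 (0.0537), ELF 1 (0.113), ELF 2 (0.684), ELF 5 (0.231).

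**Figure D3:**
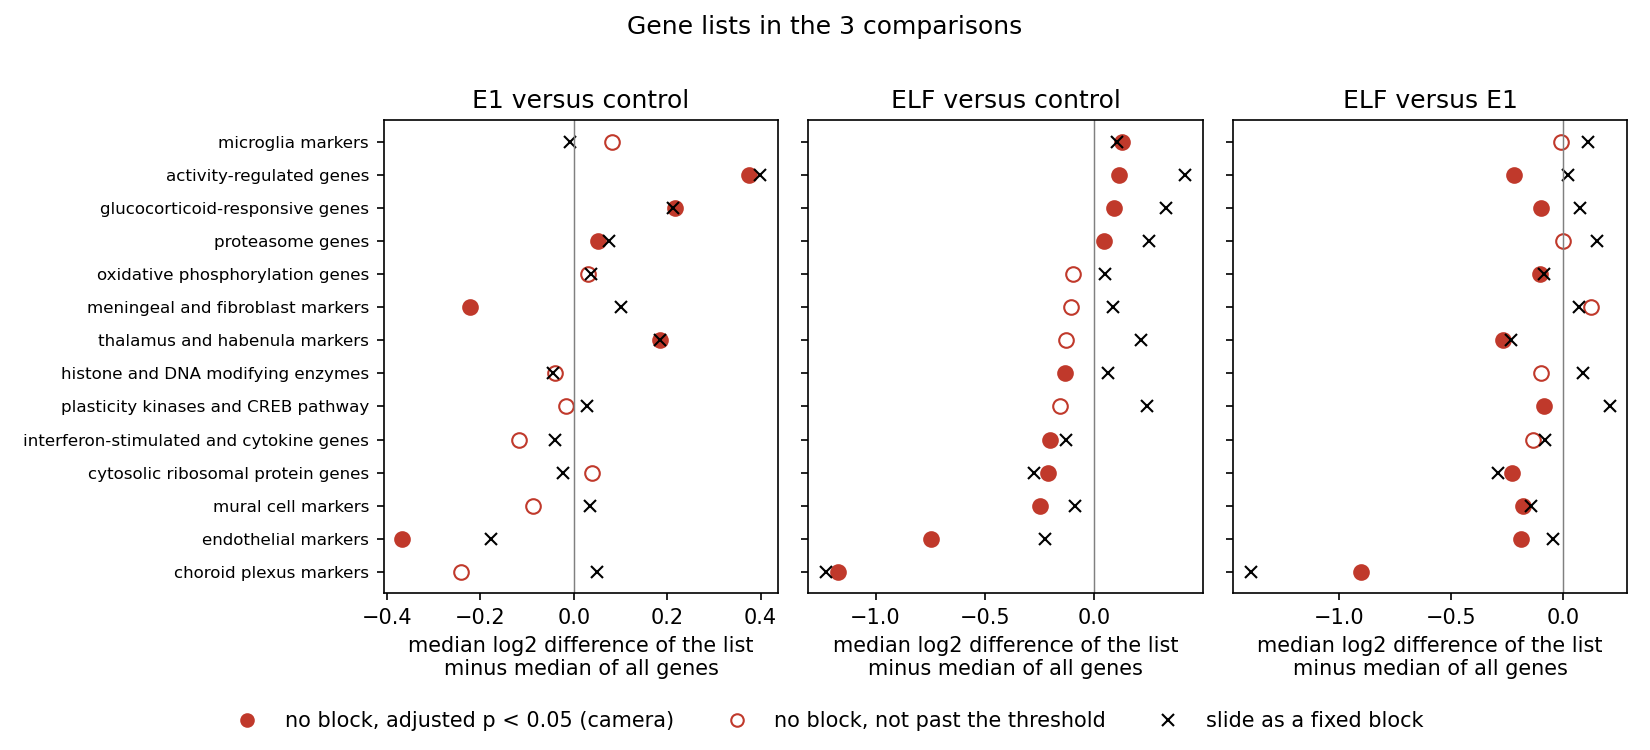
Median log2 difference of each gene list minus the median of all genes in the 3 comparisons. Circles are the fit without a block, filled where camera's adjusted p was under 0.05, and crosses the fit with slide as a fixed block. The activity-regulated list lies right of 0 in both fits of E1 versus control, at 0.38 without the block.

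Genes changed against control in E1 and in ELF overlapped. Dusp1, Cldn5, Kdr, Sox18, Edn1, Eomes, Clspn, Zcchc5, Ppp1r14d and Myo15 were among 26 genes called in both, 19 higher and 7 lower, and none went in opposite directions. Independent lists of these sizes would share 0.507 higher and 0.0911 lower genes. In 100 simulations of unchanged groups with shared controls and no slide effect no gene was called in both. With the slide correlation of 0.467 added, 7.02 genes on average were called in both with the same direction (highest 27), and 1 of 100 simulations reached 26. With the 5 controls split into 2 and 3, the mean overlap over 20 splits was 0.05 genes and the highest 1, so the overlap was not seen with separate controls, where fewer arrays remained. The log2 differences of all genes correlated across genes, which are not independent, at 0.755, against 0.50 in the simulations, 0.619 in those with a slide effect and 0.595 with split controls. Their covariance was 0.0951, against 0.0285, 0.0784 and 0.0799 in that order. In simulation a slide effect alone thus gave part of this overlap on average, and all of it in 1 of 100 runs. Genes were drawn independently of each other there, so these ranges may be too narrow.

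The chemokine genes Cxcl5 and Ccl3 were the 2 genes called between ELF and E1. Cxcl5 was -2.0 in E1 and -0.38 in ELF relative to control, and Ccl3 -0.78 and -0.13. Of the 35 genes that rose in E1, 33 lay closer to control in ELF, and their median difference was 1.14 in E1 and 0.71 in ELF. Of the 14 that fell, 13 lay closer to control. These genes were chosen for passing in E1, which favours a smaller value in another group.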

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

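The tests of the activity-regulated genes within slide 2 and both tests of the choroid plexus on the third ELF array were chosen after those results were seen, and the other tests of this part beforehand. That a value must pass its bound by more than its error was also required only after values had been seen, for the Igf2 test and for the activity-regulated genes on slide 2, and it changed the reading of the Igf2 test alone. For the activity-regulated genes that error was the range over 3 E1 arrays, each against the same 1 control array (0.307 to 0.355). It holds no spread between control mice. Values here are log2 intensities relative to the array's 75th percentile for genes, and medians relative to the mean of the 15 arrays for gene lists. Of 553 groups of 5 arrays tested, 43 held an array far from the other 4 for its range, and chance gives this in about 1 in 20 groups.

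Choroid plexus markers lay at -2.58 on the third ELF array, against -0.26 to -0.0228 on the other 4, with Ttr at -1.81, Sostdc1 at -1.57 and C230095G01Rik (now Tmem72) at -5.62. Against a weak array, no other list fell further below the other 4 ELF arrays than -0.41. On this array 100% of the 24 markers were lower than on each of the other 14. A piece of tissue with little choroid plexus is a candidate explanation, but that share describes the pattern and does not tell it from lower expression within the choroid plexus, which stays open. For Igf2, which the choroid plexus makes, the difference between ELF and control was -0.90 (SE 0.21, limma adjusted p = 0.0477), and -0.52 (SE 0.19, limma adjusted p = 0.201) with the marker mean as a covariate. That kept more than the 50% set beforehand as speaking against choroid plexus content, but by less than its error, so content and a lower Igf2 level in the tissue cannot be told apart, and no biological explanation was tested. Without the third ELF array the Igf2 difference was -0.73 (limma adjusted p = 0.0622).

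Calls against control may follow the slide that held 4 of the 5 controls. With control 5 held out, its median position between the other controls (0) and E1 (1) was 0.93 over 4099 genes called without it, and that between controls and ELF 0.867 over 636 genes. Held-out controls of slide 1 reached at most 0.467 and 0.295. Kng1 lay at -5.06 on control 5, against -8.79 to -8.55 on the other controls, and Tlr8 at -5.95, against -8.93 to -8.70. For endothelial markers the position of control 5 was 0.462, at which the slide and a lower level after extinction trials cannot be told apart.

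Activity-regulated genes in E1 were higher than in control also where both groups shared a slide, with a median of 0.36 on slide 2, and by 0.38 relative to all genes with quantile normalization. The value with quantile normalization argues against unequal signal distributions as the whole cause. Within slide 2 the rise did not draw on other slides, but only 1 control array lay there. A deviation of that 1 mouse cannot be told from a group difference, so this test cannot exclude the slide. A response to the return to the shock context may explain the rise, as a hypothesis found and tested on the same data, and handling or the time since the last exposure of control mice, which the labels do not give, stays open. Neither description of the control mice includes a shock, and no shocked mice without a return were measured. The return and the earlier shock therefore cannot be told apart.

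Other splits of the 10 arrays of a comparison into 5 and 5 were fitted without the other group, 100 per comparison with the real one included. For E1 versus control 3 splits gave at least the 31 genes of the real one, counted over the 26052 genes without missing values. Arrays of a slide were correlated, so the splits are not interchangeable and cannot exclude chance for that count. The highest other split gave 4054 genes. That split set controls 1 to 4 with E1 2 against the rest, the other as large as the real one, with 910 genes, controls 1 to 4 with E1 3, and both follow slide 1, which points to a structure of the arrays by slide. Both leave 2 replicate numbers unparted, and controls 1 to 4 with E1 5, which parts all 5 numbers, gave 4. Under a fixed slide block 3 genes were called. For ELF versus control the real split gave 0 genes by limma, with 6001 genes at an unadjusted p under 0.05 in the fit of all arrays. All 100 splits give at least 0, so these splits decide nothing about chance there. The highest other split, controls 1 to 4 with ELF 4, gave 3546 genes and also follows slide 1, and slide as a block called 81. For ELF versus E1 the real split gave 0 genes by limma too, with 2517 genes at an unadjusted p under 0.05 in the fit of all arrays, and all 100 splits again give at least 0 and decide nothing. The highest other split, E1 1 to 3 with ELF 3 and 4, gave 3897 genes. It holds slides 2 and 4 apart, as the real one does, and exchanges the arrays of slide 3, and the slide block called 5040. For gene lists, 54 splits gave at least the 7 of E1 versus control (highest other 14), 31 the 10 of ELF versus control (highest other 20) and 61 the 8 of ELF versus E1 (highest other 21), and chance cannot be excluded for these counts.

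The second ELF array stood apart from the other 4 in these genes: Ccl3 -4.22 (others -4.47 to -4.41), Dbp 4.15 (others 3.32 to 3.39), Fkbp5 -0.45 (others 0.0831 to 0.24), Kdr -1.28 (others -0.98 to -0.91), Pcp4 4.61 (others 4.21 to 4.28), Prkcb1 3.83 (others 4.27 to 4.42), Psma7 4.61 (others 4.18 to 4.30), Psmb7 1.93 (others 1.77 to 1.80), Ptprb -2.43 (others -0.65 to -0.12), Rpl36 4.43 (others 4.07 to 4.10), Tac1 0.00869 (others -0.57 to -0.42), Tyrobp 1.46 (others 0.37 to 0.48). In gene lists it stood apart for oligodendrocyte markers 0.0706 (others -0.0186 to 0.00407), microglia markers 0.22 (others 0.0517 to 0.0994).

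The fifth E1 array stood apart in Dnmt3a 0.10 (others -0.75 to -0.67), Mll3 2.02 (others 2.30 to 2.36), Nxph4 0.20 (others -0.46 to -0.30), Ogn -1.76 (others -0.42 to -0.0662), Psmc3 2.44 (others 2.23 to 2.27), Rgs5 0.60 (others 0.26 to 0.33), and in the lists of CA2 and CA3 pyramidal cell markers 0.0437 (others -0.0263 to -0.0104), GABA receptor genes -0.11 (others 0.00859 to 0.042). Other E1 arrays stood apart in Klf4 -0.23 (others -0.97 to -0.76) on E1 1, Cd83 0.50 (others 0.41 to 0.44), Pappa -2.81 (others -3.74 to -3.53) and circadian clock genes -0.0137 (others 0.0445 to 0.063) on E1 2, and Clca3 -4.63 (others -5.59 to -5.35) and striatum markers -0.00612 (others 0.0593 to 0.0846) on E1 4.

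Control 5 stood apart from the other controls in Arfl4 -0.63 (others -1.14 to -1.0), Ntrk2 3.87 (others 4.15 to 4.27), Pappa -3.62 (others -3.97 to -3.89). Control 1 did so for endothelial markers 0.71 (others 0.13 to 0.28), dentate granule cell markers -0.17 (others 0.0284 to 0.081), and control 3 for CA1 pyramidal cell markers -0.12 (others -0.0103 to 0.0212). Among the other ELF arrays, Egr2 was -0.47 on ELF 3, Tlr8 was -6.60 on ELF 4 and Rgs14 was 2.46 on ELF 5.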

How the results depend on the processing

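Quantile normalization combined with slide as a block, the fits without ELF arrays 2 and 4, and the replicate block in a fit of only the control and E1 arrays were chosen after seeing the data, and all other alternatives before the data were examined. Signal over background limits dim genes: with a probe well above background on all arrays the counts were 64, 769 and 4 for E1 versus control, ELF versus control and ELF versus E1, in the order used throughout this part, against 49, 548 and 2 as reported. The counts of all 3 comparisons stayed within 1.5 times without a filter and with the mean of a gene's probes. The cause was not tested for the changes below unless stated.

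Genes called were 446, 1712 and 5 with quantile normalization, 291, 1142 and 0 with the median as the shift, 39, 638 and 0 with normexp background, and 240, 1587 and 11 with the authors' values. They were 84, 772 and 2 with trend and robust eBayes, 5810, 14691 and 8386 with array weights, 25, 148 and 20 with the choroid plexus covariate, and 32, 0 and 0 with only the 2 groups compared. At an adjusted p under 0.01 they were 8, 0 and 0, by construction. With slide as a fixed block they were 3, 81 and 5040, as a random block 0, 0 and 0 by limma (3419, 6001 and 2517 at an unadjusted p under 0.05 as reported), and within the slide that holds both groups 0 and 0 for E1 versus control and ELF versus E1, where 3 E1 arrays met 1 control array and 2 ELF arrays met 2 E1 arrays. Quantile normalization with the slide block gave 5, 48 and 898. Without ELF arrays 2 and 4, ELF versus control gave 998 and ELF versus E1 0.

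Gene lists past the threshold were 6, 10 and 9 as reported, 1, 0 and 1 with an estimated correlation, 4, 3 and 1 with fry, 6, 4 and 2 with the slide block, 9, 8 and 5 with a random slide block and 6, 3 and 2 with quantile normalization and the slide block. With the controls split into 2 and 3, the 26 genes shared by E1 and ELF became 0.05 on average, where fewer controls remained.

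Leaving out 1 array moved the genes called between 8 (without control 2) and 1117 (without control 5) for E1 versus control, between 0 (without control 2 or control 3) and 5123 (without ELF 4) for ELF versus control, and between 0 and 11 (without ELF 3) for ELF versus E1. Lists past the threshold ranged from 3 to 11, from 6 to 12 and from 6 to 12. Of 2020 values of named genes with 1 array left out, 1618 kept direction and side of the threshold, 351 lost the threshold, 50 passed it and none that was called reversed. The remaining 1, Fkbp5 in ELF versus E1 without ELF 2, was not called and changed sign (0.0853).

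With the replicate number as a block, 12, 215 and 0 genes and 5, 7 and 8 lists passed, and in the fit of only control and E1 arrays 3148 genes and 5 lists. Same-numbered control and ELF arrays deviated together at over 0.1 in 2 of 5 pairs (lowest -0.435) and E1 and ELF arrays in 1 of 5 (lowest -0.4), with 1 and 0 closest to their own number, so for these comparisons the arrays share only a number. The replicate block changed no other call of a named gene or list in E1 versus control than those printed with the comparison.

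Of the values of named genes, the slide block reversed Tpbpa (-0.47), Tlr8 (-1.41), Olfr91 (-0.29), Capza3 (-0.73) and Klra17 (-1.07) in ELF versus control. With quantile normalization and the block, Tlr8 (-0.48), Klra17 (-0.28), Eltd1 (0.0743), Klf4 (0.0045), Acsbg1 (-0.0439) and Map3k15 (0.19) reversed there. No other alternative reversed a named gene that was called. Values not called changed sign in 24 of 199 with the slide block and 31 of 199 with quantile normalization and the block, in 10 of 110 within the shared slide and 7 of 202 with the mean of a gene's probes, and in at most 2 with any other. With the slide block 101 of 199 values kept direction and threshold, and with quantile normalization 173 of 202 did.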

Other observations

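All values in the first paragraph come from lists and genes fixed before the data were examined, and the choice of what to describe was made after seeing them. Eomes, a marker of intermediate progenitors, fell in ELF versus control by 0.59 (SE 0.12, limma adjusted p = 0.0313) and had fallen in E1, while the 24 immature neuron and proliferation markers as a list did not pass in either comparison (camera adjusted p = 0.86 and adjusted p = 0.859). Ccnb1, a cyclin of dividing cells, rose in ELF by 0.76 (limma adjusted p = 0.045), though 1 of its 2 other probes differed in the opposite direction. Among hippocampal subfield markers Map3k15 fell in ELF by 0.53 (limma adjusted p = 0.0299), while the CA2 and CA3 list did not pass (camera adjusted p = 0.373). The astrocyte gene Acsbg1 rose in ELF by 0.35 (limma adjusted p = 0.0499), and Nxph4 by 0.78 (limma adjusted p = 0.0424). Under a fixed slide block these differences were -0.84 for Eomes, 0.65 for Ccnb1, -0.23 for Map3k15, 0.06 for Acsbg1 and 0.08 for Nxph4. In 10 fits with 1 array left out the limma threshold was missed by Eomes in 6, Ccnb1 in 7, Map3k15 in 5, Acsbg1 in 8 and Nxph4 in 7.

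Markers of dentate granule cells, CA1 pyramidal cells, interneurons, glutamate receptors and GABA receptors did not pass in any comparison without the block. In E1 versus control camera's adjusted p was 0.301, 0.731, 0.705, 0.86 and 0.705 in that order. The first principal component of the 15 arrays held 51.1% of the variance. The log2 distance of the array median to its 75th percentile was between -2.19 and -2.08 on the ELF arrays of slide 4, -2.50 and -2.63 on those of slide 3, and between -2.48 and -2.32 on the control and E1 arrays. Scores of the 15 arrays on the first component correlated with this distance at 0.968 in absolute value. They ran from -99.8 on ELF 2 to 98.4 on ELF 4. The largest axis of variation thus followed the signal distributions of the arrays.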
